A study of Mus musculus with 33 samples.

How the data were processed

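Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was analysed from peak lists, which give the places where a library held more tags than its background. Of the 33 samples of the series, 15 had a peak list. These were 6 lists of wild type mouse embryonic fibroblasts (MEFs) and 6 lists of HSF1 knockout MEFs, each made with the antibodies labelled CS and MM, and 3 lists of wild type MEFs made with an antibody against SRF. Each antibody was used before heat shock and after 12 and 60 min of heat shock. The other 18 samples were 12 nascent RNA (PRO-seq) libraries, among them those of cells lacking both HSF1 and HSF2, and 6 IgG or input libraries, and they were not analysed here. The labels do not name the target of CS and MM; the file headers name the experiment an Hsf1 ChIP-seq, and both were treated as HSF1 antibodies.

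The wild type CS and MM peaks were called by the authors with MACS 1.4.2 at a p cutoff of 1e-04 against the IgG library of the same time, per the file headers. The same headers name a merge of 2 replicates for these libraries and keep at most 1 tag per position. The knockout lists were called with MACS 1.4.2 at the same cutoff with no control library and from files that name no merge, per the file headers. Knockout peaks were therefore called against the local background of the same library, wild type peaks against IgG, and peak numbers are not on one scale between the genotypes. The SRF lists were called with MACS2 2.0.9 against IgG, per the file headers. The genome was mm10, per the labels, and the aligner is not given in the sources used here.

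Per the file headers and column names, each MACS 1.4.2 peak carries a tag count, a score equal to minus 10 times the log10 of its p-value, a fold enrichment over background (a ratio) and, where a control was used, an FDR in percent, all as deposited by the authors. Each SRF peak carries the pileup (a signal: tags over the summit), the -log10 of its p-value and q-value and a fold enrichment, as deposited by the authors. These are the authors' own values for each peak. They were used only to describe, rank or filter peaks within a list and were not compared between lists.

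Tags left after removal of duplicates (M stands for mega, as in megabases) numbered 25.2, 26.3 and 19.6 M in the wild type CS libraries (before, 12 and 60 min), 15.9, 17.7 and 14.0 M in the MM libraries, and 10.1, 12.3 and 9.23 M in the IgG libraries they were called against. In the knockout the CS libraries held 9.95, 5.18 and 8.97 M and the MM libraries 12.1, 15.6 and 7.39 M. The SRF libraries were shallow, with 0.751, 1.55 and 0.949 M distinct tags and 85%, 80% and 73% of tags redundant. SRF tags were 19 bp long before heat shock and 31 bp at 12 and 60 min, so SRF times differ in tag length too. Their IgG libraries kept 0.402, 0.337 and 0.488 M tags after 98% to 99% were removed as redundant. The wild type fragment length estimated by MACS was 45 bp (CS) and 40 bp (MM) before heat shock, close to the tag length of 36 bp, against 128 and 107 bp at 12 min and 161 and 114 bp at 60 min.

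There was 1 list per genotype, time and antibody. No test compared conditions, and shares of a list are given with 95% exact (Clopper-Pearson) binomial intervals, which cover counting error only. A shared region was a group of CS and MM peaks of the same genotype and time that overlapped by at least 1 bp, and it was the unit taken forward. Its summit was the midpoint of the summits of its CS and MM peaks with the most tags. The CS and MM lists of a time share their IgG library, so their overlap is not independent of that control, whose reads were not analysed here. Chance overlap was measured by moving each peak to a random place on its chromosome 1000 times (200 times between times and for positions).

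Gene positions came from the GRCm38.p6 gene table, the same primary assembly as mm10. The table gives gene starts and ends without strand, so the planned distance to a transcript start was replaced by the distance to either end of a gene, and a region with its summit within 1 kb of one is called a region at a gene end. All 49980 annotated genes were used for the position of regions, and the 21631 protein-coding genes on chromosomes 1 to 19 and X for gene lists. A protein-coding gene with a shared region at either end is called bound. The 13 gene lists hold 362 genes, all found in the table. They were fixed before the data were examined, as were the tests and most of the other settings tried. Each list was compared with all other protein-coding genes by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the 39 tests of each factor (13 lists at 3 times). Genes are not replicates and neighbours can share a region, so these p-values describe the lists at hand.

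Genes were named by a fixed rule. For each list of regions it took the 10 at a protein-coding gene end with the best mean of their CS and MM fold ranks, up to 4 bound members of each gene list in the same order, and all bound cytosolic chaperones. It also took the 5 best-ranked 60 min regions away from protein-coding gene ends and the cytosolic chaperones not bound at 60 min. For SRF the rank was that of the deposited fold. Names outside this rule are said to have been chosen after their values were seen.

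The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and overlap counts of the wild type lists were checked with bedtools 2.31.1. The gene list test was tested on simulated data over the 21631 genes, where a list with 20 bound members planted was called in 100 of 100 draws and lists without planted members in 4 of 1200. Alternatives covered the overlap required, stricter p, q and FDR thresholds, each antibody alone, the distance to a gene end, protein-coding genes only, the removal of regions that overlap a knockout peak, and the removal of chromosome M and the first 3.1 Mb of chromosome 9. Searches for heat shock elements and other motifs need the genome sequence and were not run.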

Results

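HSF1, the transcription factor that drives the heat shock response, was mapped by ChIP-seq in mouse embryonic fibroblasts (MEFs, fibroblasts grown from mouse embryos) before heat shock and after 12 and 60 min of heat shock. Antibodies labelled CS and MM were used in wild type cells and in cells lacking HSF1, which measure the background of each antibody. SRF, a factor known for binding genes of the actin cytoskeleton and immediate early genes, was mapped in wild type cells at the same times. There was 1 peak list for each of these 15 combinations and therefore no replicate error. Tag counts and fold enrichments of single peaks are the authors' values within their list.

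The first comparison asked where HSF1 was found in wild type cells at each time. Before heat shock HSF1 was already at genes of major chaperones: Hspa8, the constitutive Hsp70, Hsp90aa1 and Hsp90ab1, the cytosolic Hsp90 proteins, Hsph1, an Hsp110, and Hspd1 with Hspe1, the mitochondrial chaperonin and its co-chaperonin. Both antibodies found 121 regions before heat shock, 1412 at 12 min and 3455 at 60 min. The stress-inducible Hsp70 genes Hspa1a and Hspa1b had no CS or MM peak before heat shock and a shared region at 12 and 60 min. Of the 121 regions before heat shock, 119 (98.3%, interval 94.2% to 99.8%) overlapped a 12 min region, and 119 a 60 min region. With 50% of both regions required to overlap these shares were 12.4% and 0%, as regions were wider after heat shock (median 448, 823.5 and 997 bp), and with MM alone 40.1% and 41.6%. Of the 1412 regions at 12 min, 1241 (87.9%, 86.1% to 89.5%) overlapped a 60 min region, whereas 2224 of the 3455 regions at 60 min (64.4%) had no 12 min region under them.

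The CS lists held 180, 1781 and 4773 peaks in order of time and the MM lists 449, 1927 and 4614. The share of CS peaks that overlapped an MM peak was 67.2% (59.8% to 74.0%) before heat shock, 79.3% (77.4% to 81.2%) at 12 min and 72.4% (71.1% to 73.7%) at 60 min. The share of MM peaks that overlapped a CS peak was 26.9% (22.9% to 31.3%), 73.7% (71.7% to 75.6%) and 75.9% (74.7% to 77.2%). Randomly placed CS peaks overlapped MM peaks 0.027, 2.26 and 16.5 times on average over 1000 shuffles. St13, which encodes an Hsp70 cochaperone, shared the region with the most tags before heat shock with its neighbour Xpnpep3, at 439 CS and 305 MM tags. At 60 min the region with the most tags was at Hsp90ab1, with 1818 CS and 1429 MM tags (chromosome 17, 45570410 to 45575638).

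The calls before heat shock were the least certain. No CS peak of that time had a deposited FDR of 5% or less (range 39.5% to 100%), and at this limit 0, 941 and 2882 shared regions were left at the 3 times.

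**Figure D1:**
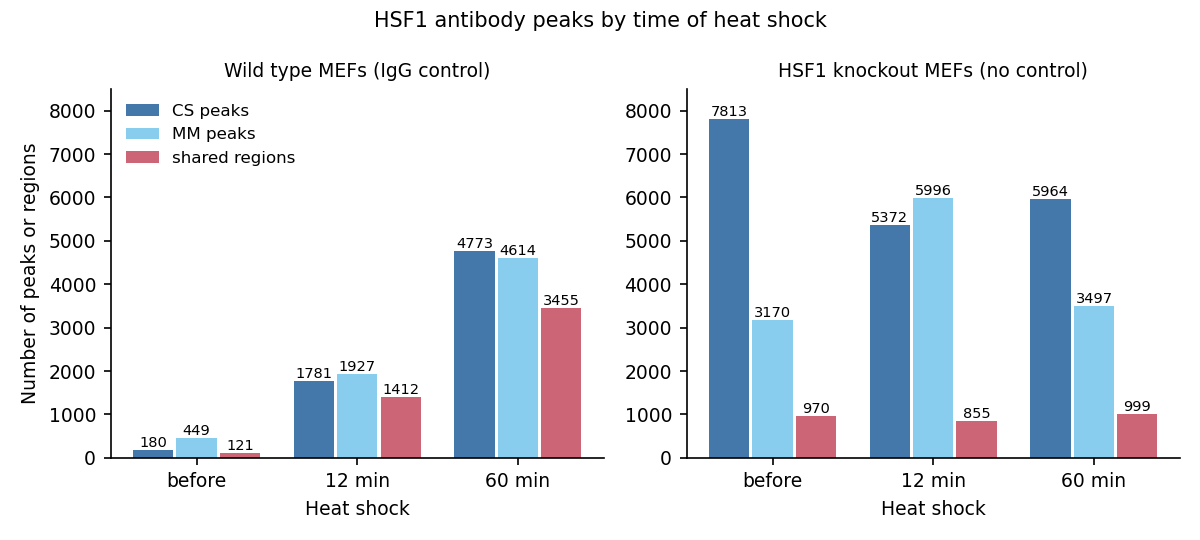
Number of peaks (y axis) in the CS and MM lists and of regions shared by both (bars), by time of heat shock (x axis), in wild type MEFs (left, called against IgG) and HSF1 knockout MEFs (right, called without a control). Shared regions rose from 121 to 3455 in wild type cells and were 970, 855 and 999 in knockout cells.

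The next comparison asked which genes lay at HSF1 regions. The list of cytosolic chaperones, which also holds Serpinh1 of the endoplasmic reticulum, had the largest share bound: 11 of 43 before heat shock (25.6%, interval 13.5% to 41.2%), 30 of 43 at 12 min (69.8%, 53.9% to 82.8%) and 29 of 43 at 60 min (67.4%). Among all other protein-coding genes 0.144% were bound before heat shock and 1.39% at 12 min. In total 42, 330 and 559 protein-coding genes were bound at the 3 times. All 42 genes bound before heat shock stayed bound at both later times, 243 were bound at 12 and 60 min but not before, 274 at 60 min only and 45 at 12 min only. Of the 171 regions at 12 min without a shared region at 60 min, 81 still overlapped a 60 min peak of CS (63) or MM (18). Genes bound at 12 min only therefore need not have lost all signal.

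The 11 genes of this list bound before heat shock were Hspa8, Hsp90aa1, Hsp90ab1, Hsph1, Dnaja1, St13, Serpinh1, Stip1, Fkbp4, Chordc1 and Ahsa1. Stip1, Ahsa1 and Fkbp4 encode cochaperones of Hsp90, and Serpinh1 encodes Hsp47, a collagen chaperone of the endoplasmic reticulum. Hspa8 had 338 CS and 255 MM tags (chromosome 9, 40800698 to 40801597, summit 46 bp from a gene end). First bound at 12 min were 19 more: Hspa1a, Hspa1b, Hspa1l, Hspa4, Hspa4l, Hspb1, Hspb2, Hspb8, Dnaja4, Dnajb1, Dnajb2, Dnajb4, Dnajb5, Dnajb6, Bag3, Ahsa2, Ptges3, Hspbp1 and Ppid. Of these, 18 were bound at 60 min as well and Dnajb6, with 117 CS and 68 MM tags at 12 min, was not. No chaperone of this list was first bound at 60 min. Hspa1b held 802 CS and 621 MM tags at 12 min (chromosome 17, 34958511 to 34960676) and 1402 and 1166 at 60 min (34956940 to 34962747). Hspa1a and Hspa1l share a region (34969888 to 34972981 at 60 min). Hspa1a and Hspa1b are near-identical copies, so the split of tags between them depends on how the authors placed such reads, which is not given in the sources used here.

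Not bound at 60 min were Hspa2, Hspa14, Hspb6, Cryab, Dnaja2, Dnajb6, Dnajc7, Bag1, Bag4, Fkbp5, Cdc37, Unc45a, Ppp5c and Stub1. Cryab, the small heat shock protein next to Hspb2, had a 60 min region inside its annotated span, 3412 bp from the nearer end.

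**Figure D2:**
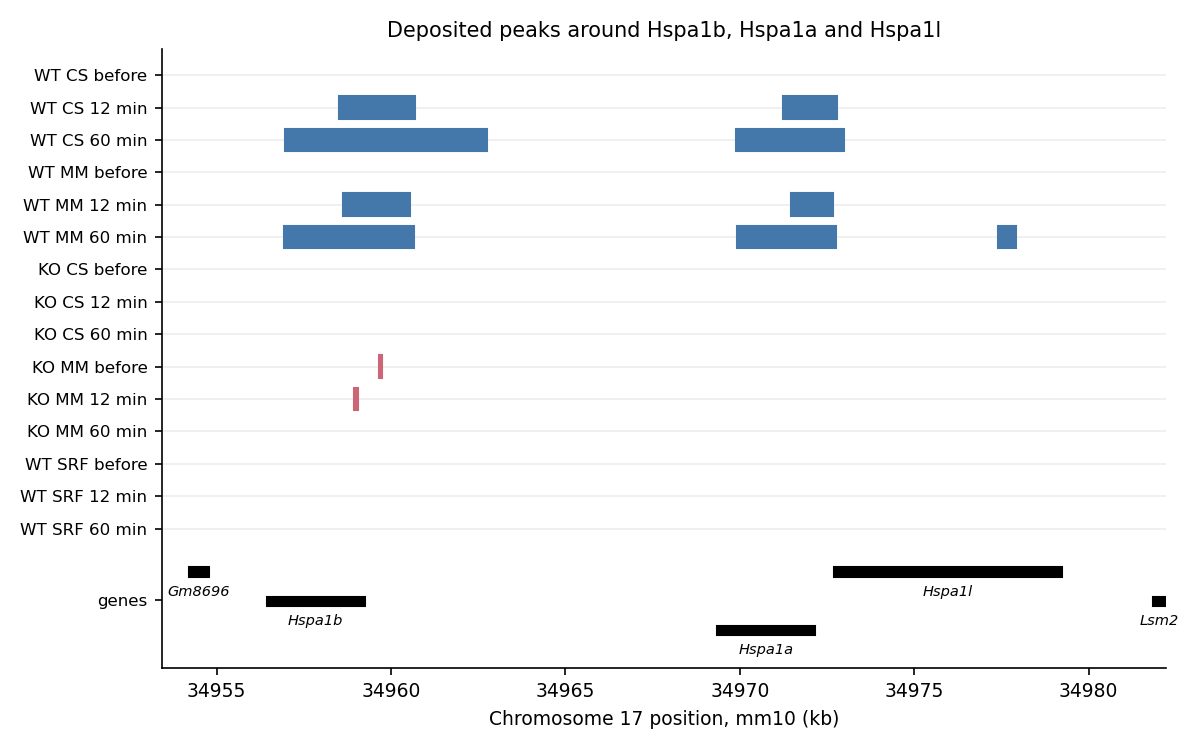
Map of chromosome 17 around Hspa1b, Hspa1a and Hspa1l (x axis, mm10 position in kb), with the deposited peaks of each of the 15 lists as boxes in rows and genes at the bottom. Wild type CS and MM lists have peaks over Hspa1b and Hspa1a at 12 and 60 min and none before; the knockout lists have 2 short MM peaks of 6 and 8 tags at Hspa1b.

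The TRiC/CCT chaperonin folds actin and tubulin. Cct3, Cct4 and Cct7 were bound before heat shock, and all 8 subunit genes on the list (Tcp1, Cct2, Cct3, Cct4, Cct5, Cct6a, Cct7 and Cct8) at 12 and 60 min, while none of the 6 prefoldin genes was. The mitochondrial chaperone genes Hspd1 and Hspe1 were bound at all 3 times through a single region between them, with 319 CS tags before heat shock, and Hspa9, the mitochondrial Hsp70, was bound at 12 and 60 min. No gene of the endoplasmic reticulum list was bound before heat shock; of this list, Hsp90b1, Pdia3 and Canx were bound at 12 min and P4hb in addition at 60 min. Ubb was bound at all 3 times, and no proteasome subunit gene was bound.

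By Fisher's exact test with adjustment over 39 tests, the cytosolic chaperone list passed at each time (adjusted p = 2.53e-20 before heat shock, 9.99e-44 at 12 min and 4.82e-35 at 60 min). The TRiC/CCT list also passed (adjusted p = 1.59e-05, 7.29e-11 and 3.87e-09), as did the mitochondrial list (adjusted p = 0.00212, 0.00681 and 0.0201) by the exact test. Endoplasmic reticulum chaperones passed at 12 min (3 of 23, exact adjusted p = 0.0176) and 60 min (4 of 23, exact adjusted p = 0.0115). The immediate early list passed at 12 min through Jun, Jund and Ccn1 (3 of 26, exact adjusted p = 0.0212) and at 60 min with Atf3 in addition (4 of 26, exact adjusted p = 0.0164).

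Actin cytoskeleton genes did not pass: Flnc, Cald1 and Wdr1 were bound at 12 and 60 min (3 of 46, exact adjusted p = 0.0918 and 0.244). Ribosomal protein genes Rplp2 and Rps13 were bound at 12 min and Rps18 and Rpl6 in addition at 60 min (4 of 51, exact adjusted p = 0.110, and 0.0374 within 500 bp). At 60 min 1 gene of the oxidative stress list (Mt1), 1 of the cell cycle list (Mki67) and the extracellular matrix genes Vim and Col5a1 were bound, and none of these lists passed. No gene of the heat shock factor list, Hsf1 and Hsf2 included, and none of the 29 markers of other cell types was bound at any time. Outside the 1 kb limit, a shared region lay 2331 bp from an end of Hsf2 at 12 min and 2363 bp at 60 min.

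Without regions that overlap any knockout peak, the calls of the mitochondrial list (exact adjusted p = 1, 0.489 and 0.691) and the immediate early list (exact adjusted p = 1 at 12 min and 0.952 at 60 min) ended, as did that of the TRiC/CCT list before heat shock (exact adjusted p = 0.0969). The endoplasmic reticulum call ended at 5 kb (exact adjusted p = 0.0658 at 12 min and 0.0834 at 60 min), at 500 bp at 12 min (exact adjusted p = 0.0774) and with MM alone at 60 min (exact adjusted p = 0.0577); the immediate early call at 12 min ended at 500 bp (0.0904) and with p of 1e-10 or less (0.469), which also ended the TRiC/CCT call before heat shock, and the mitochondrial call at 60 min ended at 5 kb (0.0953).

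**Figure D3:**
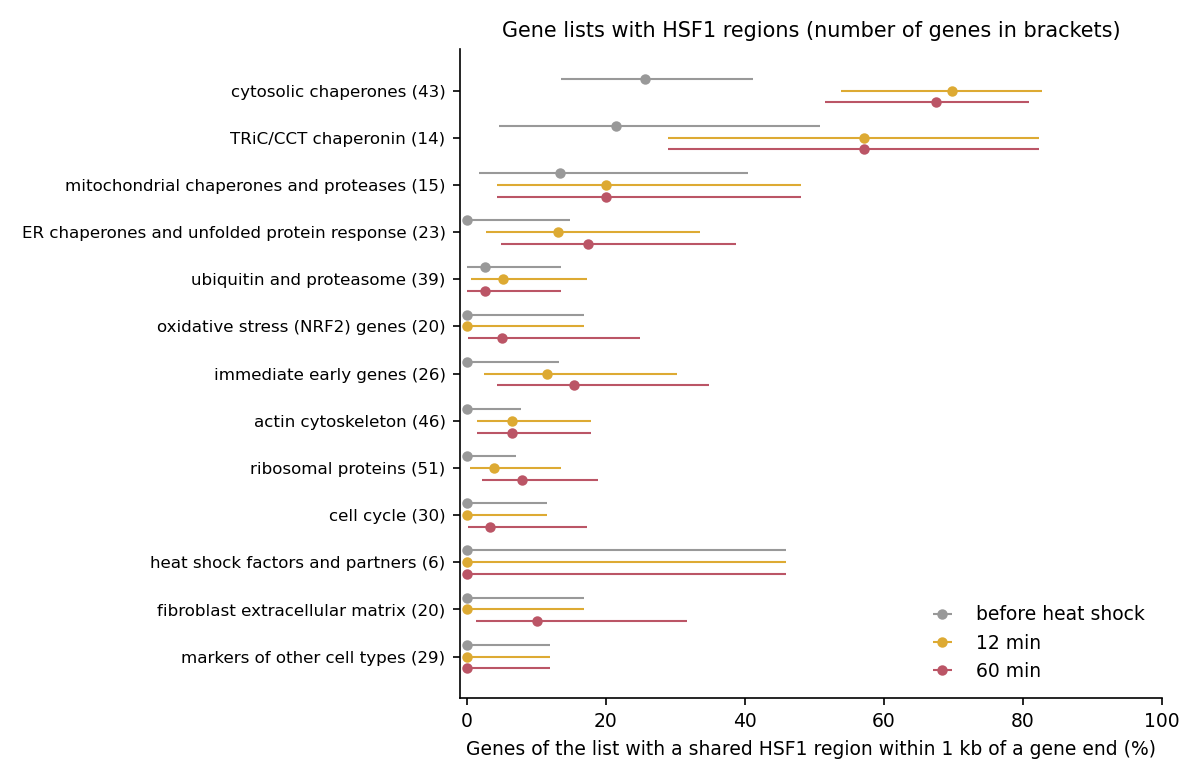
Share of the genes of each fixed list with a shared HSF1 region within 1 kb of a gene end (x axis, %), before heat shock and at 12 and 60 min (points; bars are 95% exact binomial intervals). Cytosolic chaperones went from 25.6% to 69.8% and 67.4%, and the markers of other cell types stayed at 0 of 29.

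Regions at gene ends were also ranked by fold enrichment within each list; the lists differ in length, so the ranks are not compared between times. Before heat shock the first 10 were at the chaperone genes St13 (with Xpnpep3), Hspa8, Hspd1 with Hspe1, Hsph1, Hsp90ab1 (2 regions around 1 end), Serpinh1 and Hsp90aa1, and at Ints2 and Rsrp1. At 12 min the list was led by Chordc1 (122 CS fold), Swt1 with Trmt1l (123 CS fold), Serpinh1, Ahsa1 with Vipas39 and Ints2. At 60 min Etnk2 led (226 CS and 227 MM fold; chromosome 1, 133380510 to 133381432), followed by genes outside the fixed lists (Fadd, Ints2, Lrrc61, Zfand1, Anxa11, Clu, Cacybp and Dscaml1), with Hspa4l as the only listed chaperone gene among the first 10 regions. Clu encodes clusterin, an extracellular chaperone. By CS tags of the same list, regions of chaperone genes were high, with 1818 at Hsp90ab1, 1402 at Hspa1b, 1275 at Hspd1 with Hspe1 and 1225 at Hsph1.

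The position of regions relative to genes was compared next. The best-ranked 60 min regions away from protein-coding gene ends lay inside Gm14616 (chromosome 2, 174858034 to 174859229), Srgap1 (chromosome 10, 121902213 to 121905032), Sh3kbp1 (chromosome X, 159837070 to 159838186) and Otogl (chromosome 10, 107899364 to 107900813), and outside genes on chromosome 17 (67472971 to 67474020). All 5 were also shared at 12 min and none overlapped a knockout peak; the Srgap1 region was also present before heat shock. Regions at the end of any annotated gene made up 34.7% before heat shock (42 of 121, interval 26.3% to 43.9%), 26.3% at 12 min (372 of 1412, 24.1% to 28.7%) and 19.5% at 60 min (674 of 3455, 18.2% to 20.9%). Of the 60 min regions, those already present before heat shock were at gene ends in 35.04% (26.5% to 44.4%), those first shared at 12 min in 25.3% (22.8% to 28.0%) and those first shared at 60 min in 15.8% (14.3% to 17.4%). Regions inside genes but away from their ends made up 34.7% before heat shock and 48.6% at 60 min, against 46.2% and 45.6% in shuffles, and regions outside genes 30.6% and 31.9%, against 47.2% and 47.9%.

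**Figure D4:**
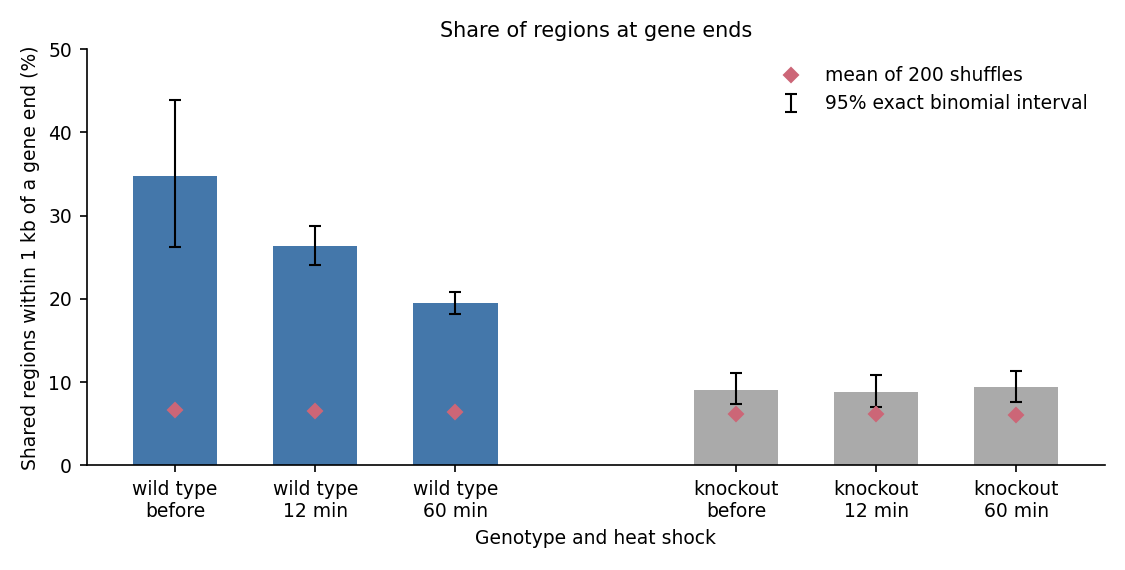
Share of shared regions within 1 kb of an annotated gene end (y axis, %; bars with 95% exact binomial intervals) by genotype and time of heat shock (x axis); diamonds are the mean of 200 shuffles on the same chromosomes. Wild type shares fell from 34.7% to 19.5% and knockout shares were 9.07%, 8.77% and 9.41%.

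The knockout lists asked how much of this signal is found without HSF1. No gene of the cytosolic chaperone, TRiC/CCT, mitochondrial or endoplasmic reticulum lists had a region found by both antibodies in the knockout at any time. The best-ranked knockout regions at gene ends were instead at Rps29, Oasl1, Mthfd1l, Naaa, Gcgr, Lars2 and Asmt at all 3 times. Mt1, which encodes a metallothionein, was the only listed gene with a knockout region at each time. The wild type region at Mt1 at 60 min overlapped no knockout peak. Acta2 had a knockout region at 12 min and Ier3 and Ccn2 at 60 min. Of the list tests the immediate early list passed at 60 min (2 of 26, exact adjusted p = 0.0333).

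Of the wild type shared regions, 12 of 121 (9.92%, interval 5.23% to 16.7%) overlapped a knockout peak of either antibody before heat shock, 56 of 1412 (3.97%, 3.01% to 5.12%) at 12 min and 115 of 3455 (3.33%, 2.76% to 3.98%) at 60 min. Shuffled regions did so 0.287, 6.58 and 15.4 times on average. Regions found by both antibodies in the knockout overlapped 0, 1 and 1 wild type regions, against 0.029, 0.484 and 1.655 on average in shuffles. Counts this low are near chance and cannot show that background was absent. Most peaks of the knockout lists were short and low, with a median length of 84 to 107 bp and a median of 4 to 7 tags. Each of these lists also held 591 to 870 peaks with p of 1e-10 or less, and its highest peak had 5024 to 9654 tags. The knockout peaks inside wild type regions were of the low kind, with medians of 116, 93 and 103 bp and of 6, 5 and 5 tags. Every one of them had p above 1e-10. At 12 min 8 of the 30 bound genes of the cytosolic chaperone list had a region with such a peak from some knockout list, among them Dnajb1 (6 tags), Hsp90ab1 (8 tags) and Hspa1b (8 tags). The region of Hspd1 and Hspe1 overlapped a knockout peak of 5 tags, and the 12 min regions of Jun and Ccn1 overlapped knockout peaks of up to 10 and 18 tags.

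Knockout lists held 7813, 5372 and 5964 CS peaks and 3170, 5996 and 3497 MM peaks, of which 970, 855 and 999 regions were shared. Of the 970 regions before heat shock, 639 (65.9%, 62.8% to 68.9%) were found at all 3 times. Because these lists were called without a control and from fewer tags, the overlap with wild type depends on a different threshold, and with knockout peaks of any time it was 17.4%, 11.7% and 8.86%.

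The SRF lists asked where SRF was found across the same heat shock. Egr1, an immediate early gene, had an SRF peak at all 3 times, 346 to 380 bp from the gene end, and so did Zswim6, whose peak had the highest fold before heat shock and at 12 min. Map3k14, Sertad1, Homer1, Mob3a and Izumo4 had a peak before heat shock and at 12 min. At 12 min peaks were added at Tpm1, a tropomyosin gene (chromosome 9, 67049236 to 67049521), Mus81, Vdac2 and Dynlt1b. At 60 min the only protein-coding genes with a peak at an end were Egr1, Zswim6 and Ubald1.

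There were 64, 68 and 18 SRF peaks at the 3 times, with a pileup of 3, 4 and 4 tags at the median. Of the 64 peaks before heat shock, 15 (23.4%, interval 13.8% to 35.7%) overlapped a 12 min peak and 3 a 60 min peak. No gene list passed the exact test: the immediate early list had 1 of 26 genes at each time (exact adjusted p = 0.187, 0.355 and 0.140) and the actin cytoskeleton list 1 of 46 at 12 min (exact adjusted p = 0.466). Within 5 kb both passed at 12 min, the actin list with 4 of 46 genes (exact adjusted p = 1.84e-05) and the immediate early list with 3 of 26 (exact adjusted p = 1.19e-04). The immediate early list also passed within 5 kb before heat shock with 2 of 26 (exact adjusted p = 9.87e-04).

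SRF peaks were compared with the HSF1 regions of each time. None of 64 SRF peaks overlapped a shared HSF1 region before heat shock, 14 of 68 did at 12 min (20.6%, interval 11.7% to 32.1%) and 5 of 18 at 60 min (27.8%, 9.69% to 53.5%), against at most 2 in any of 1000 shuffles. The HSF1 list before heat shock is short, and 0 of the 68 SRF peaks at 12 min overlapped its 121 regions, while 2 and 3 of the 64 SRF peaks before heat shock overlapped the HSF1 regions of 12 and 60 min. The genes at these peaks were listed after their values were seen. At 12 min the peaks lay at ends of Myl12a with Myom1, Sf3b2, Ermard with Tcte3, and Gm3417, inside Wdr1, Myh9, Medag and Gm31718, and otherwise away from genes. Their strength varied: the peak in Wdr1 had a pileup of 5 tags (-log10 q of 4.69), those at Myl12a and Sf3b2 3 tags (1.29 and 0.53) and that in Myh9 2 tags (0). At 60 min they lay inside Atxn1, Nell2, Ano6 and Npas4 and once away from genes, and the 3 SRF peaks with the highest fold were among them: Nell2 (14 tags, 21.9), chromosome 17 at 65961509 (8 tags, 9.98) and Atxn1 (5 tags, 3.77). With summits required within 200 bp the counts were 5 at 12 min and 3 at 60 min, and 2 at 12 min and 2 at 60 min with p of 1e-10 or less.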

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

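Of the tests in this part, those of sequencing depth, of knockout peaks in gained regions and in regions away from gene ends, and of the strongest 60 min regions were chosen only after the result was seen; the test in regions away from gene ends replaced 2 earlier ones, whose outcome the few knockout overlaps had fixed.

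SRF and HSF1 moved in opposite directions to 60 min. From 12 to 60 min the CS list rose from 1781 to 4773 peaks and the MM list from 1927 to 4614, while the SRF list fell from 68 to 18. From before heat shock to 60 min the CS list rose from 180 to 4773 and the MM list from 449 to 4614, while the SRF list fell from 64 to 18. This difference between the factors rests on 1 list each and was not tested. The SRF libraries kept 0.751, 1.55 and 0.949 M tags, of 19, 31 and 31 bp.

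Regions shared by CS and MM rose from 121 to 1412 and 3455 with heat shock. Deeper sequencing is argued against by the tags: the higher of the CS and MM ratios of 60 over 12 min was 0.790, while regions rose 2.45 times, and from before heat shock to 12 min tags rose 1.04 (CS) and 1.11 times (MM), while regions rose 11.7 times. Antibody background without HSF1, as far as the knockout lists show it, is argued against as the main source. Of the regions gained by 60 min, 8.48% (283 of 3338, interval 7.55% to 9.47%) overlapped any knockout peak. Of all 3455 regions at 60 min 306 did so, against 46.7 on average in shuffles, so background in a minority of regions is not excluded. The knockout lists were called without a control and from fewer tags, so background below their threshold is not covered. Lower calling sensitivity before heat shock stays open: 53.8% (44.4% to 63.1%) of the 117 strongest 12 min regions by CS tags were called before heat shock, between the limits of 50% and 80% set for the test. The estimated fragment length of 45 and 40 bp at that time could have lowered that sensitivity. Binding induced by heat shock, which the design varies, stays open beside it. Sensitivity before heat shock has no part in the later rise, from 1412 regions at 12 min to 3455 at 60 min.

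The share of regions at gene ends fell from 34.7% to 19.5%, with regions at chaperone genes such as Hspa8 and Hsp90ab1 among the earliest. Antibody background away from genes, as far as the knockout lists show it, is argued against: 60 min regions away from gene ends overlapped a knockout peak less often (6.65%, 185 of 2781) than those at gene ends (17.95%, 121 of 674), with an odds ratio of 0.326 (0.253 to 0.421), and 0.321 (0.228 to 0.453) within 200 bp of the summit. Weak 60 min calls away from genes stay open because the ranking decides the outcome. Of the 121 strongest 60 min regions by fold rank 16.5% (10.4% to 24.4%) were at gene ends, which went against this explanation, but by CS tags 47.1% and by MM tags 52.1% were, which went with it. A later spread of HSF1 to places away from gene ends, over the course of heat shock, cannot be told apart from this.

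Of the SRF peaks, 14 of 68 at 12 min and 5 of 18 at 60 min overlapped HSF1 regions, and 0 of 64 did before heat shock, when there were only 121 HSF1 regions to overlap. HSF1 signal carried over into the SRF libraries stays open: the 19 overlapped HSF1 regions had a median percentile of 81.2 (57.7 to 91.9) by CS tags, between the limits of 75 and 90 set for the test. The median was 82.6 for the 14 regions at 12 min and 71.1 for the 5 at 60 min (range 33.8 to 97.9), and the 60 min peak with the highest fold, in Nell2, lay in an HSF1 region at percentile 36.7, which goes against carry-over for that peak. Antibody background that does not need HSF1 also stays open. The knockout lists were made with CS and MM, so they cannot measure the background of the SRF antibody. Of these SRF peaks 26.3% (5 of 19, interval 9.15% to 51.2%) lay in a knockout peak. Among all SRF peaks the share was 18.75% (12 of 64) before heat shock, 14.7% (10 of 68) at 12 min and 16.7% (3 of 18) at 60 min. Binding of SRF next to HSF1 under heat shock could not be told apart from carry-over or background with 19 peaks.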

How the results depend on the processing

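Alternatives chosen only after the data were seen were the FDR and q limits, CS or MM alone for the number of shared regions, p of 1e-10 or less for HSF1 gene lists, at least 20 tags for knockout peaks, SRF without chromosome M and the first 3.1 Mb of chromosome 9, and the removal of knockout overlaps for ends shared by 2 genes. Of 536 values under an alternative, 436 were the same within their limits, 79 moved, 14 lost and 7 gained a call, and 0 reversed. The call of the cytosolic chaperone list held at all 3 times under each of the 6 alternatives run for it, which did not include the FDR limit. No paired analysis was possible because there was 1 list per group and no test between groups. For the same reason no replicate could be left out, though CS and MM were each also used alone. The wild type CS and MM lists came from merged replicates, which could not be separated here. The 4 planned motif alternatives were not run, since no genome sequence was used here. Where no reason is given, the cause was not tested.

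In order of time, shared HSF1 regions were 31, 646 and 1750 with p of 1e-10 or less, as fewer peaks enter, 0 and 941 before heat shock and at 12 min with FDR of 5% or less, and 449 before heat shock with MM alone. The share of regions before heat shock kept at 12 min was 12.4% with an overlap of at least 50% of both regions, 100% with p of 1e-10 or less, 40.1% with MM alone and 57.9% with FDR of 5% or less at the later time. The share kept at 60 min was 0%, 100% and 41.6% for the first 3 of these. The share of 12 min regions kept at 60 min was 76.1% with 50% overlap, 92.9% with p of 1e-10 or less, 85.9% with CS alone, 75.9% with MM alone and 84.5% with the FDR limit. The share of 60 min regions present at 12 min was 31.1%, 34%, 31.7% and 31.6% for the first 4 of these. The fall with 50% overlap follows from wider regions after heat shock.

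The share of wild type regions in a knockout peak was 0.826%, 0% and 0% with 50% overlap, 17.4%, 11.7% and 8.86% with either antibody at any time, 0%, 0.142% and 0.0579% with both antibodies, and 0%, 0% and 0% with p of 1e-10 or less. The wild type share at gene ends was 53.7%, 48.4% and 43.0% within 5 kb. At 12 and 60 min it was 19.6% and 13.4% within 500 bp, 19.97% and 14.0% for protein-coding genes only, and 23.3% and 17.6% without regions overlapping any knockout peak. The knockout share was 6.08%, 4.80% and 5.51% within 500 bp, 30.2%, 30.3% and 31.5% within 5 kb, and 3.40%, 3.51% and 3.90% for protein-coding genes only. The SRF share within 5 kb was 23.4% before heat shock and 50% at 60 min. Wider or narrower windows change these shares by construction.

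HSF1 gene lists past the threshold were 1, 3 and 3 without regions overlapping any knockout peak and 3 at 12 min within 500 bp. SRF gene lists past the threshold within 5 kb were 1 before heat shock and 2 at 12 min. SRF peaks were 5, 16 and 3 with p of 1e-10 or less and 23, 35 and 9 with q of 0.05 or less. SRF peaks overlapping HSF1 regions were 5 at 12 min and 3 at 60 min with summits within 200 bp, 2 and 2 with p of 1e-10 or less, and 5 at 12 min with q of 0.05 or less. SRF peaks before heat shock found at 12 min were 1 with p of 1e-10 or less and 6 with q of 0.05 or less. Knockout regions shared by both antibodies were 564, 410 and 588 with p of 1e-10 or less and 305, 138 and 216 with at least 20 tags. The SRF libraries, with 0.751 to 1.55 M tags, limit what the SRF lists could hold.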

Other observations

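The tests of this part were planned except for the shuffles and the removal of regions with a knockout peak in the last paragraph, which were chosen only after the result was seen, as were the genes named here.

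Oxidative stress genes lay near HSF1 regions at 60 min but mostly further than 1 kb from them. Within 5 kb of a gene end, 7 of the 20 genes of this list had a shared region (exact adjusted p = 2.47e-04): Hmox1, Srxn1, Txnrd1, Osgin1, Fth1, Mt1 and Mt2. Hmox1 encodes heme oxygenase, Fth1 a ferritin chain, and Mt1 and Mt2 metallothioneins. Of these, Fth1 was also near a region at 12 min (1868 bp), and Mt1 was the only one within 1 kb. With MM alone and 1 kb, 4 of 20 were bound at 60 min (exact adjusted p = 0.0380).

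SRF peaks near actin genes at 12 min also lay mostly outside 1 kb. Besides Tpm1, SRF peaks were 1790 bp from an end of Actg1, 1306 bp from Cfl1 and 1172 bp from Wdr1, and among immediate early genes 2269 bp from Egr3 and 1764 bp from Mcl1. Actg1 encodes cytoplasmic gamma actin and Cfl1 cofilin.

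Each knockout list held 40 to 63 peaks on chromosome Y, and the wild type and SRF lists held 0.

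A hypothesis was that HSF1 regions favour places where several protein-coding genes end within 1 kb of each other, as for Hspd1 and Hspe1. At 60 min 79 of 496 bound gene-end clusters (15.9%) held 2 or more genes, against 2995 of 38130 unbound clusters (7.85%; odds ratio 2.22, exact p = 4.47e-09). Clusters with more genes are wider (median 2244 against 2001 bp), and shuffled regions gave 9.75% on average, with 2 of 200 shuffles as high as observed. Without regions that overlap any knockout peak the share was 14.4% (odds ratio 1.96, exact p = 1.45e-05). The result is consistent with the hypothesis, but active promoters, which were not measured here, could explain it as well.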
